A study of Mus musculus with 12 samples.

How the data were processed

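DNase-seq was done by the submitters on G1E and G1E-ER4 cells, asynchronous or arrested with nocodazole and sorted for phosphorylated histone H3, with 3 libraries in each of 4 groups. Per the labels' protocols, cells were lightly fixed with formaldehyde, digested with DNase I at 3 concentrations per condition, and sequenced after a DNase-seq library preparation. The submitters' processing notes name Bowtie and the mouse build mm9. The version of Bowtie, the peak caller and its filters are not given in the sources used here.

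The deposited files are peak lists without headers, 1 per library and 1 per group in which the authors pooled the replicates, 16 in all. Each line gives a position, the offset of the summit and a signal per peak. The signal is the value the authors' peak caller gave to each peak, with an unstated normalization, in the deposited lists. Each list holds exactly 100000 peaks in descending order of signal, so the authors limited the lists by rank. This makes the number of peaks the same in every sample and pushes a list with fewer strong sites to reach further down into weak ones. It also means that a list with a flatter signal curve can miss sites that lie just below its limit. Signals were therefore used only to rank peaks within a list, and comparisons rest on position. Peak lists give no read counts, so depth per library and counting intervals could not be stated, and differences in depth between stages remain unmeasured. The pooled lists were used only as an alternative and to look up named regions.

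Peaks on the 19 autosomes and X entered the comparisons. Chromosome Y held 2 to 7 peaks per list and the mitochondrial genome 1, and these were left out. Regions were the union of the 12 replicate lists, merged where peaks shared at least 1 bp, and a region counted as present in a list with a peak of that list overlapping it by at least 1 bp. No 2 files were identical. Positions are on mm9 and counted from 1.

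Overlap of 2 lists was the Jaccard index in base pairs. It cannot exceed the ratio of the smaller to the larger covered length, so it also depends on peak width. The test statistic was the mean index of pairs from the same group minus that of pairs from different groups. Recovery was measured on regions of 2 of the 3 asynchronous lists of a line, as the share found in the left-out asynchronous list and in each mitotic list, each list being left out in turn. Tests were exact permutation tests, two-sided, with stage labels exchanged within line or line labels within stage. They have 20 arrangements per stratum and 400 combined. The smallest p of the overlap test is 0.1 within a stratum and 0.01 combined. The recovery test treats the stages unequally, so its smallest p is 0.05 within a line and 0.0025 combined. The threshold was 0.05. Presence was not tested region by region. Within a line or stage an exact test of 3 lists against 3 cannot go below p = 0.1, and over both strata such a test was not run. Regions were counted where all lists of a group and no list of the other had them, and the counts were compared with those of other splits of the libraries.

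The named regions are, for each contrast and direction, the 5 with the best mean rank among those present in all 6 lists of a group and in none of the other 6. This rule, the tests and the alternatives listed next were fixed before the data were examined. The alternatives were leaving out each library, the 50000 highest peaks of each list, autosomes only, overlap of at least 0.5 of the shorter interval, shares of overlapping peaks, presence in at least 2 of 3 lists, the authors' pooled lists, and exchange of labels only between libraries of the same replicate number. Chosen after seeing the data were a window of 300 bp around each summit, the 20000 highest peaks, leaving out chromosomes 1, 2, 4, 12 and 14, and leaving out both replicate 1 libraries of G1E, as were all results per chromosome.

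No gene annotation or genome of build mm9 was used here. The gene table at hand is of assembly GRCm38.p6, and positions were not converted. Therefore 4 intended results were not analysed here, namely the recovery of promoter against distal regions, the promoter share of peaks, the gene lists and the sequence motifs. The lists fixed for them (erythroid, progenitor, mast cell, megakaryocyte and other lineage genes, and factor motifs) have no result.

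Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The procedure was tested on simulated data for the stage comparison, with lists drawn from the 265371 regions at their observed frequencies. All 200 regions made asynchronous-only were found, beside 12 others. The 200 were bound to be found, since they were given the very pattern that is counted, so this checks only the calculation. A simulated loss of 15.3 percentage points in recovery was estimated as 15.3. In 20 simulations without a difference, the recovery test and the overlap test each fell below 0.05 in 1. The simulated lists had no rank limit, no flatter mitotic curve and no difference in peak width between libraries. They therefore do not show how the tests behave where such features differ between stages. A simulated difference of -18.3 points between X and autosomes of the same rank was estimated as -19.7.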

Results

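Chromatin accessibility was measured by DNase-seq, which maps the sites where DNase I cuts chromatin most readily, in 12 libraries of 2 murine erythroid cell lines. G1E cells lack GATA1, a transcription factor required for red cell maturation. G1E-ER4 cells are their derivative with an estradiol-inducible GATA1, and were given 100 nM estradiol for 22 h. Each line was sampled as asynchronous culture and as mitotic cells, which were arrested with 200 ng/ml nocodazole for 7 h and sorted for phosphorylated histone H3. Each of the 4 groups had 3 libraries. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The series asks how far accessible sites persist in mitosis. Its lines add whether the sites differ with GATA1 restoration, which came with estradiol in every G1E-ER4 library.

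Each list held the 100000 peaks of highest signal on build mm9, so the number of peaks is set by a rank limit and carries no biological difference. Read depth is unknown from these files. Merging the 12 lists on the autosomes and X gave 265371 regions. All 12 lists shared 16323 of them (6.15%), and 122837 (46.3%) came from 1 list. Shared regions were the strong ones: a median over lists of 92.5% of the 10000 highest peaks lay in a region of all 12 lists, against 14.1% of the 10000 lowest peaks. The asynchronous lists fell off more steeply. Their signal at rank 10000 was 4.58 ± 1.58 times that at rank 100000 in G1E and 4.00 ± 0.227 times in G1E-ER4 (SD, n = 3 each). In mitotic lists the same ratio was 2.31 ± 0.413 and 2.15 ± 0.106 (SD, n = 3 each).

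The main comparison asked how many sites accessible in asynchronous cells were also found in mitosis. Of all peaks of the asynchronous lists, reproduced or not, mitotic lists held 46.7% ± 1.65 in G1E and 54.2% ± 7.80 in G1E-ER4, and other asynchronous lists 58.0% ± 5.30 and 64.3% ± 7.62 (SD, n = 3 each). Sites reproduced between asynchronous lists were mostly found. Regions of 2 asynchronous G1E lists were found in 61.4% ± 6.03 of cases in a mitotic G1E list (SD, n = 3), and the same regions were found in the left-out asynchronous list in 85.0% ± 2.27 of cases (SD, n = 3). In G1E-ER4 the mitotic lists held 70.2% ± 3.88 of the regions and the left-out asynchronous lists 84.7% ± 3.00 (SD, n = 3 each). Recovery in mitosis was thus 72.2% of the replicate level in G1E and 82.9% in G1E-ER4. All 6 mitotic lists, at 54.4% to 72.9%, lay below all 6 asynchronous ones, at 81.8% to 87.8%. Over both lines the deficit in mitosis was 19.0 percentage points (exact permutation test, two-sided, labels exchanged within line, p = 0.0025, the smallest that its 400 arrangements allow). Within G1E the deficit was 23.6 points and within G1E-ER4 14.5 points, each with an exact permutation p = 0.05, the smallest that 20 arrangements allow. The G1E deficit was 15.5 or 14.1 points without its asynchronous replicate 2 or 3, 15.2 without both replicate 1 libraries and 14.6 among the 20000 highest peaks, the last 2 settings chosen after seeing the data, and the G1E-ER4 deficit 8.62 without its asynchronous replicate 3. The flatter signal curve of the mitotic lists can by itself lower their recovery, and the deficit was not corrected for it.

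**Figure D1:**
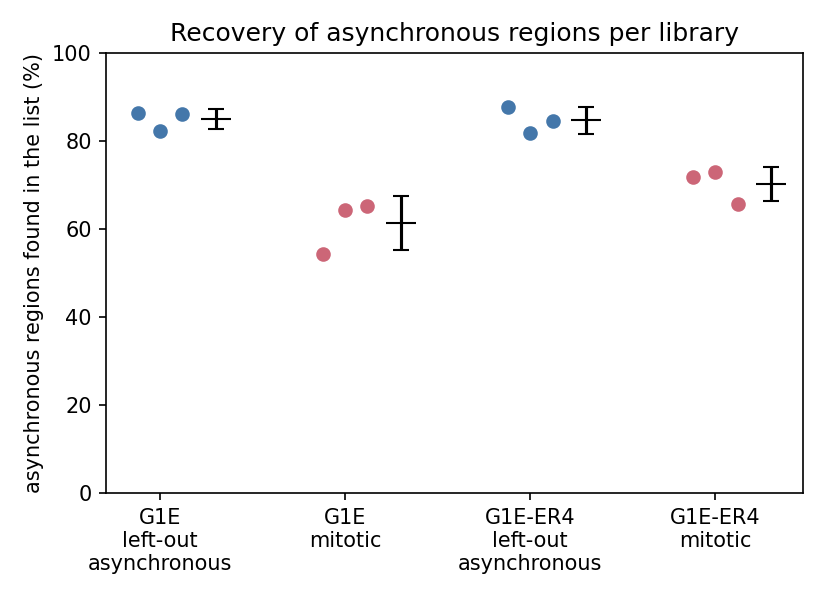
Percentage of regions of 2 asynchronous lists found in each left-out asynchronous list and each mitotic list, per cell line; points are libraries and bars the mean with SD (n = 3). The mitotic libraries sit between 54.4% and 72.9%, all below the asynchronous ones.

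Of the regions present in all 3 asynchronous lists, 40695 in G1E and 41333 in G1E-ER4, a mitotic list held 66.7% ± 7.38 and 75.2% ± 3.52 (SD, n = 3 each). At least 1 mitotic list of the line held 80.6% of these regions in G1E and 87.9% in G1E-ER4, and all 3 held 51.1% and 61.3%. Overlap by position alone was lower. The same regions displaced by 500 kb met a peak of a mitotic list in 23.7% ± 1.89 of cases in G1E and 29.3% ± 3.12 in G1E-ER4 (SD, n = 3 each).

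Recovery in mitosis followed the strength of the site. The 10000 strongest peaks of the asynchronous lists were found in mitotic lists at 95.5% ± 4.61 in G1E and 99.2% ± 0.392 in G1E-ER4, against 99.5% ± 0.265 and 99.9% ± 0.00764 in the other asynchronous lists (SD, n = 3 each). At ranks 10001 to 20000 the mitotic lists held 75.5% ± 13.7 in G1E and 77.8% ± 5.41 in G1E-ER4, against 96.7% ± 2.96 and 98.6% ± 0.950 in other asynchronous lists (SD, n = 3 each). The gap was widest in the next class. At ranks 20001 to 30000 the mitotic lists held 53.3% ± 11.8 of the peaks in G1E and 62.8% ± 5.37 in G1E-ER4, against 89.7% ± 7.18 and 89.6% ± 3.74 in other asynchronous lists (SD, n = 3 each). At ranks 90001 to 100000 the mitotic share was 27.5% ± 4.50 in G1E and 30.9% ± 9.90 in G1E-ER4, and the asynchronous share was 23.5% ± 5.10 and 34.6% ± 11.4 (SD, n = 3 each), differences within the spread between libraries. No test was made across ranks. With 300 bp around each summit in place of the whole peak, a setting chosen after seeing the data, the mean over lines for the 10000 strongest peaks was 90.4% in place of 97.3%. For ranks 90001 to 100000 it was 14.9% in place of 29.2%.

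**Figure D2:**
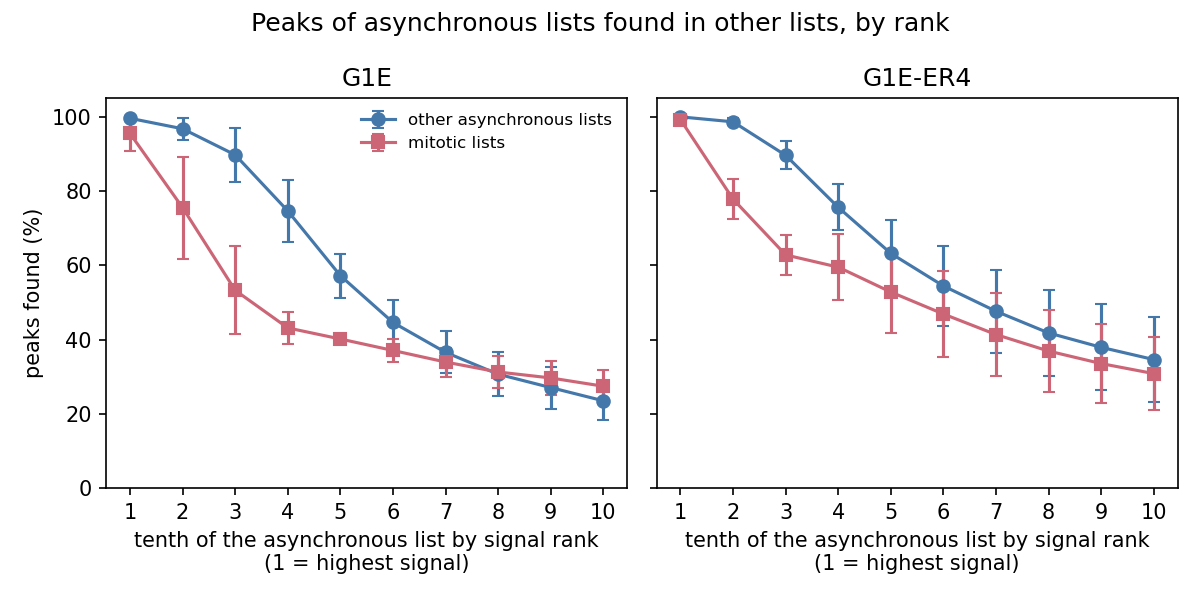
Percentage of peaks of the asynchronous lists found in the other asynchronous lists (circles) and in the mitotic lists (squares) of the same line, in 10 classes of 10000 peaks ordered by signal; error bars are SD over 3 lists. The curves start at 95.5% or more and lie farthest apart at ranks 20001 to 30000.

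The same question put to the mitotic regions gave smaller gaps. Regions of 2 mitotic lists were found in asynchronous lists at 65.4% ± 4.71 in G1E, against 81.2% ± 5.56 in the left-out mitotic list (SD, n = 3 each). In G1E-ER4 the values were 79.5% ± 4.60 and 81.2% ± 6.57 (SD, n = 3 each), a gap of 1.64 points that was within the spread between libraries. This direction was described and not tested.

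Overlap of whole peak sets differed less clearly by stage. In G1E the Jaccard index, the shared base pairs divided by all base pairs covered, averaged 0.329 between asynchronous lists, 0.417 between mitotic lists and 0.252 between stages. In G1E-ER4 the means were 0.386, 0.367 and 0.364. Same-stage pairs exceeded different-stage pairs by 0.0670 over both lines (exact permutation test, two-sided, p = 0.05 over 400 arrangements), which did not fall below the 0.05 threshold. The excess was 0.121 in G1E (exact p = 0.1, the smallest 3 against 3 allows) and 0.0132 in G1E-ER4 (exact p = 0.9). Without asynchronous replicate 1 the G1E excess was 0.196, and with 300 bp around each summit, a setting chosen after seeing the data, 0.0619. The G1E-ER4 excess turned to -0.00618 without asynchronous replicate 3, and was 0.0523 in shares of overlapping peaks (exact p = 0.1) and 0.0519 among the 20000 highest peaks (exact p = 0.5). Over both lines, counting overlapping peaks in place of base pairs gave an excess of 0.0977 with an exact p = 0.01, and without replicate 1 of asynchronous or of mitotic G1E-ER4 the Jaccard excess was 0.0750 or 0.0792 with an exact p = 0.01 each. Without asynchronous replicate 2 or mitotic replicate 3 of G1E-ER4 it was 0.0616 or 0.0607 with an exact p = 0.04 each. Without any 1 of the 3 mitotic G1E lists it was 0.0489 to 0.0619 with an exact p = 0.11 each, and without asynchronous replicate 1 of G1E 0.105 (exact p = 0.05). Among the 50000 and the 20000 highest peaks it was 0.0828 (exact p = 0.04) and 0.0802 (exact p = 0.02), and with 300 bp around each summit 0.0476 (exact p = 0.01), of which the first setting was planned and the others were chosen after seeing the data.

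A set of 902 regions was present in all 6 asynchronous lists and absent from all 6 mitotic ones. By line, 7880 regions in G1E and 5020 in G1E-ER4 had this pattern, and sets of these sizes drawn independently from the 103666 regions of at least 3 lists, the fewest that such a set needs, would share 382. Those 103666 include the 16323 regions of all 12 lists, which can enter no such set. The numbers for independent sets are therefore too low, here and for the line comparison. The 902 regions were narrow, with a median width of 638 bp, and of middle strength, with a median mean rank of 37732. The authors' pooled lists held all 902 in both asynchronous groups, and 47 of them in mitotic G1E and 29 in mitotic G1E-ER4. The opposite set, present in all mitotic and no asynchronous lists, had 72 regions, from 5809 in G1E and 1123 in G1E-ER4, where independent sets would share 62.9. As that number is too low, the 72 regions are not read as an excess. These were wider, at a median of 1664 bp, and weaker, with a median mean rank of 58012. Single lists weighed on both counts: without replicate 1 of asynchronous G1E-ER4 they were 1428 and 532, and without G1E mitotic replicate 2, G1E mitotic replicate 3 or G1E-ER4 mitotic replicate 3 the smaller count was 114, 118 or 146. Within lines, leaving out single lists raised the asynchronous-only count to at most 12366 in G1E (asynchronous replicate 1) and 8232 in G1E-ER4 (asynchronous replicate 2, with 7936 without replicate 1). The mitotic-only count of G1E became 9433 or 10029 without mitotic replicate 1 or 3, and that of G1E-ER4 became 2446, 4060 or 3382 without mitotic replicate 1, 2 or 3 and 3113 or 1727 without asynchronous replicate 1 or 2.

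The asynchronous-only regions with the best mean rank over the 6 lists are given on mm9 by position, since no annotation of that build was used. The first spans chromosome 2 from 92014274 to 92014926 and had a mean rank of 15430 ± 7803 (SD, n = 6). The second spans chromosome 4 from 135540253 to 135541596, with a mean rank of 15447 ± 6451 (SD, n = 6). The others lie on chromosome 16 from 58661710 to 58662532, on chromosome 3 from 108098834 to 108100080 and on chromosome 13 from 58389130 to 58389764, with mean ranks of 16017, 17159 and 17501. The chromosome 3 region also had a peak in the pooled mitotic G1E list, and the chromosome 13 region in both pooled mitotic lists, so their absence from the replicate lists did not extend to the pooled ones. Of the mitotic-only regions, the highest placed spans chromosome 12 from 72665299 to 72666750, with a mean rank of 28857 ± 13947 (SD, n = 6). It was followed by chromosome 1 from 14168479 to 14169680, at 30604 ± 2845 (SD, n = 6), and chromosome 1 from 58707807 to 58708762, at 33194. The last is also in the pooled asynchronous G1E-ER4 list. Chromosome 4 from 8700661 to 8703131 and chromosome 12 from 83084332 to 83086526 had mean ranks of 36123 and 38658.

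Whether the deficit in mitosis differed between the lines was tested directly. Every G1E-ER4 library had estradiol and no G1E library is labelled with it, so this test cannot separate GATA1 from estradiol or line. The deficit was 9.07 percentage points larger in G1E than in G1E-ER4, which was not detectable against the spread between libraries (exact permutation test, two-sided, line labels exchanged within stage, p = 0.26, 400 arrangements). The difference turned to -5.86 points (exact p = 0.44) among the 20000 highest peaks, a setting chosen after seeing the data, and to -0.382 points (exact p = 0.97) without replicate 3 of asynchronous G1E. The overlap excess by stage was 0.108 larger in G1E than in G1E-ER4 (exact permutation p = 0.085).

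The second comparison set G1E-ER4 with restored GATA1 against GATA1-null G1E. Same-line pairs of lists overlapped more than different-line pairs, by a Jaccard index of 0.0551 over both stages (exact permutation test, two-sided, p = 0.02, 400 arrangements). In asynchronous cells the excess was 0.0940 (exact p = 0.1, the smallest possible) and in mitotic cells 0.0162 (exact p = 0.3). The mitotic excess turned to -0.00325 without replicate 1 of mitotic G1E and was 0.0462 and 0.0315 without replicates 1 and 2 of mitotic G1E-ER4, and 0.00684 to 0.00822 without any 1 of the other 3 mitotic lists. Without replicate 1 of asynchronous G1E the asynchronous excess was 0.154 and the combined one 0.0851. The mean index between lines was 0.263 in asynchronous and 0.376 in mitotic cells. Mean covered length differed more between the lines in asynchronous lists, at 71.9 Mb in G1E and 118 Mb in G1E-ER4, than in mitotic ones, at 109 and 100 Mb. Unequal covered lengths limit the index, and their part in these values was not measured. The combined call ended, at exact permutation p = 0.05 to 0.12, without any of the 3 mitotic G1E or any of the 3 asynchronous G1E-ER4 lists. The lowest combined excess on leaving out a list was 0.0418, without replicate 1 of asynchronous G1E-ER4. With 300 bp around each summit, a setting chosen after seeing the data, the combined excess was 0.0301 (exact permutation p = 0.02). It was then 0.0492 in asynchronous and 0.0110 in mitotic cells.

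Regions present in every list of G1E-ER4 and none of G1E, at both stages, numbered 225, from 5205 in asynchronous and 1423 in mitotic cells, where independent sets would share 71.4. They were wide, with a median of 2042 bp, and 182 of the 225 (80.9%) lay on chromosome 2, which held 7.28% of all regions. Most of these, 178, lay beyond position 156000001 of chromosome 2, a limit set from the step in peak density between these same lists, where the 6 G1E-ER4 lists had 205 ± 26.7 peaks per Mb and the 6 G1E lists 76.7 ± 19.6 (SD, n = 6 each). Every G1E-ER4 list, at 171 to 243 peaks per Mb, exceeded every G1E list, at 51.8 to 103. The ratio of this density to that of the rest of the chromosome was 6.29 ± 0.912 in G1E-ER4 and 2.40 ± 0.554 in G1E (SD, n = 6 each), given without a test because the part was chosen for this difference. Chromosome 2 as a whole held 10.5% ± 0.810 of peaks in asynchronous and 10.2% ± 0.525 in mitotic G1E-ER4, against 6.40% ± 0.283 and 7.32% ± 0.801 in G1E (SD, n = 3 each). That difference of 3.48 points had an exact permutation p = 0.005, and 0.1 after adjustment over 60 comparisons, so it did not pass. Among the 20000 highest peaks, a setting chosen after seeing the data, the difference was 2.82 points (exact permutation p = 0.005, adjusted 0.0333 over 60 comparisons) and passed. Outside distal chromosome 2 that leaves 47 G1E-ER4-only regions. The number for independent sets was not computed without that part, so these 47 are not read as an excess. Without G1E mitotic replicate 2 or G1E-ER4 mitotic replicate 3 the 225 became 382 or 351. The asynchronous count of 5205 became 9678 or 9357 without asynchronous replicate 2 or 3 of G1E-ER4 and 7882 without replicate 1 of asynchronous G1E. The mitotic count of 1423 became 2795, 4385 or 3725 without mitotic replicate 1, 2 or 3 of G1E-ER4 and 2200 or 2358 without mitotic replicate 1 or 2 of G1E.

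**Figure D3:**
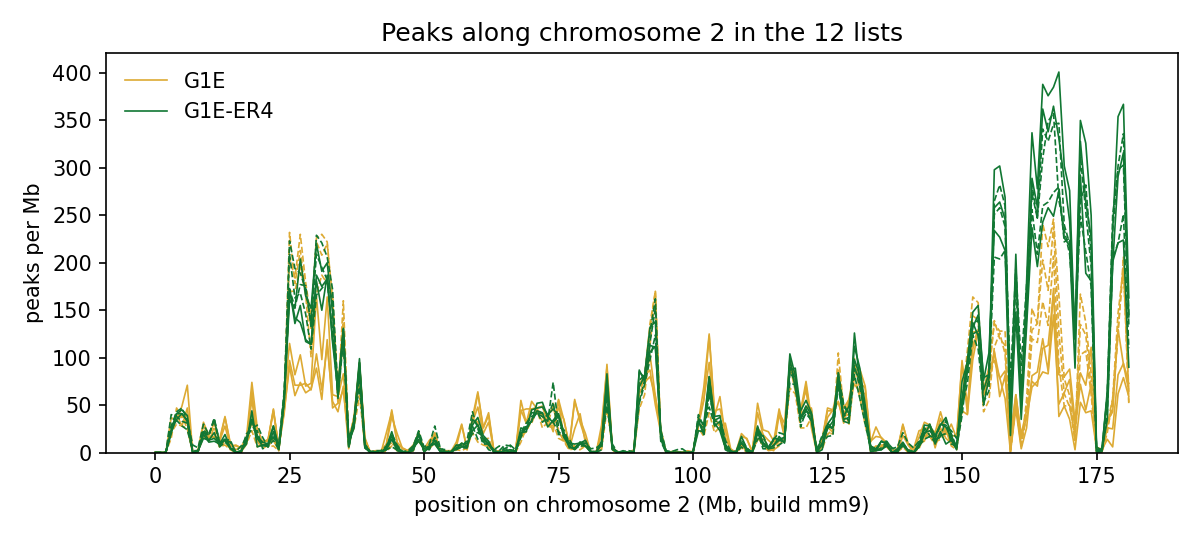
Peaks per Mb along chromosome 2 (mm9) in each of the 12 lists, coloured by cell line, with solid lines for asynchronous and dashed lines for mitotic libraries. Beyond 156 Mb the G1E-ER4 lists average 205 peaks per Mb and the G1E lists 76.7.

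The best-ranked G1E-ER4-only regions included 3 of this part of chromosome 2, from 181152541 to 181156642, from 173489110 to 173491932 and from 168984931 to 168988331, with mean ranks of 15338, 16870 and 20651. The middle of these also had a peak in both pooled G1E lists. The others were chromosome 16 from 50525911 to 50527072, with a mean rank of 15774 ± 6648, and chromosome 12 from 29522529 to 29523947, at 20370 ± 8614 (SD, n = 6 each). Regions of every G1E list and no G1E-ER4 list numbered 95, from 5700 in asynchronous and 1543 in mitotic cells, against 84.8 for independent sets, and none lay on distal chromosome 2. The number for independent sets is too low, as said above, so the 95 regions are not read as an excess. Their median mean rank, 34287, was the best of the 4 sets. The first spans chromosome 12 from 4082209 to 4083391 and had a mean rank of 8990 ± 3419 (SD, n = 6). Chromosome 6 from 57484587 to 57486195 followed at 9245 ± 6823 (SD, n = 6), and chromosome 13 from 113461743 to 113463952 at 10039 ± 5180 (SD, n = 6). Chromosome 4 from 99720573 to 99725407 and chromosome 8 from 47672960 to 47673814 had mean ranks of 11144 and 12714. All 5 were in both pooled G1E lists and in neither pooled G1E-ER4 list. Without G1E mitotic replicate 1, G1E mitotic replicate 2 or G1E-ER4 asynchronous replicate 1 the 95 became 433, 156 or 180. The asynchronous count of 5700 became 8887 to 9805 without any 1 asynchronous G1E list, and the mitotic count of 1543 became 3261 to 4788 without any 1 mitotic G1E list and 2858 or 2601 without mitotic replicate 1 or 2 of G1E-ER4.

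Median peak width did not differ detectably. It was 510 ± 218 bp in asynchronous and 775 ± 168 bp in mitotic G1E, and 805 ± 335 bp and 677 ± 228 bp in G1E-ER4 (SD, n = 3 each). Mitotic lists were wider by 68.2 bp over both lines (exact permutation test, two-sided, p = 0.645) and G1E-ER4 lists wider than G1E lists by 98.2 bp over both stages (exact p = 0.55). On leaving out single libraries these differences ranged from 6.83 to 165 bp and from 1.42 to 161 bp. Among the 20000 highest peaks the difference by stage was 265 bp (exact p = 0.39), and without the replicate 1 libraries of G1E that by line was 202 bp (exact p = 0.29). The covered length, 45.1 to 181 Mb per list, varied with the width.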

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

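The comparison of region counts with other splits and that of recovery between the lines were fixed before the data were examined. The criterion of the former was written after the results were seen, and all other tests of this part were chosen after. The effect of mitosis was compared between the 2 lines for 23 results, namely recovery, overlap, median width and the share of peaks on each of 20 chromosomes. None passed an exact permutation test with line labels exchanged within stage, after Benjamini-Hochberg adjustment for the chromosomes. For median width the change with mitosis in G1E-ER4 minus that in G1E was -393 bp (exact permutation p = 0.19). Of the 20 chromosomes, 4 had an unadjusted exact p under 0.05. Single outlying libraries were not tested for within the groups of 3.

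The counts of stage-specific and line-specific regions were set against other splits of the same libraries. For stage, both directions together gave 974 regions in both lines. Of the 100 splits, only 1, the real one, gave as many, and the highest other gave 388. For line, the real split gave 320 regions in both stages and was again the only 1 of 100 to reach that number, the highest other giving 90. Both combined counts thus exceeded those of all other splits, a share under 0.05, which does not cover each direction alone. For line, 178 of the 225 G1E-ER4-only regions lay on distal chromosome 2 and 47 elsewhere. The splits were not counted without that part, so the line count does not speak for the rest of the genome. Within a single line or stage the 10 splits are too few for a share under 0.05. There the real values were 13689 regions in G1E and 6143 in G1E-ER4 for stage, with highest others of 1525 and 2570. For line they were 10905 in asynchronous and 2966 in mitotic cells, with highest others of 1687 and 1986.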

How the results depend on the processing

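The settings of the last paragraph were chosen after seeing the data, and those of the others before. Over 29 values, 533 alternative values were computed, of which 409 kept direction and side of the threshold or stayed within their limits, 102 moved, 8 became weaker, 9 became stronger and 5 turned sign. Some of the 409 could not change, such as the overlap excess of a line when a list of the other line was left out. The deficit of recovery in mitosis over both lines kept its direction and stayed below the threshold in every setting run. It was 24.1 percentage points among the 50000 highest peaks and 14.3 to 20.02 on leaving out single libraries, with 14.1 to 25.5 in G1E and 8.62 to 15.9 in G1E-ER4. Median width differences stayed undetectable, at 6.83 to 165 bp by stage and 1.42 to 161 bp by line on leaving out single libraries, and 138 and 148 bp among the 50000 highest peaks. Depth cannot be read from the lists, and it limits every count here. Overlap by 0.5 of the shorter interval moved no count or recovery, because each peak lies inside its merged region. The recovery of promoters, gene lists and motifs was not run. The cause of the changes below was not tested, except where stated.

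On leaving out single libraries, counts of the line or stage concerned rise by construction, because fewer lists must have or lack a region. The other counts change only through the merging of regions, and some fell slightly. Asynchronous-only regions then numbered 960 to 1428 in both lines, 7880 to 12366 in G1E and 5021 to 8232 in G1E-ER4, and mitotic-only regions 81 to 532, 5815 to 10029 and 1121 to 4060. G1E-only regions numbered 100 to 433 at both stages, 5701 to 9805 in asynchronous and 1542 to 4788 in mitotic cells, and G1E-ER4-only regions 247 to 382, 5212 to 9678 and 1422 to 4385. The Jaccard excess by stage ranged from 0.0489 to 0.105 over both lines (exact permutation p = 0.01 to 0.11) and from -0.00618 to 0.0375 in G1E-ER4. The excess by line ranged from 0.0418 to 0.0851 (exact permutation p = 0.02 to 0.12) and, in mitotic cells, from -0.00325 to 0.0462. The difference between lines in the deficit ranged from -0.382 to 15.0 points. With 2 asynchronous lists the recovery reference is 1 list, which also changes this measure by construction.

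Among the 50000 highest peaks, the excess by stage was 0.0828 (exact permutation p = 0.04). Mitotic-only regions numbered 3573 in G1E and 644 in G1E-ER4, G1E-only regions 1007 in mitotic cells, and G1E-ER4-only regions 3155 in asynchronous and 857 in mitotic cells. The excess by stage in shares of overlapping peaks was 0.0977, and 0.0961 with overlap by 0.5 of the shorter peak (exact permutation p = 0.01 each). With presence in at least 2 of 3 lists, asynchronous-only regions numbered 2796 in both lines, 19134 in G1E and 12766 in G1E-ER4, and mitotic-only regions 814, 15960 and 7555. G1E-only regions numbered 794 at both stages, 15910 in asynchronous and 8618 in mitotic cells, and G1E-ER4-only regions 1199, 15292 and 7949. In the authors' pooled lists, asynchronous-only peaks numbered 9287 in both lines, 42766 in G1E and 35004 in G1E-ER4, and mitotic-only peaks 6650, 48266 and 28481. G1E-only peaks numbered 4779 at both stages, 38084 in asynchronous and 31943 in mitotic cells, and G1E-ER4-only peaks 7312, 44279 and 30328. These are larger by construction, as 1 list stands for 3. Of pooled asynchronous peaks, 57.2% in G1E and 65.0% in G1E-ER4 met a pooled mitotic peak, a difference of 7.76 points.

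Over all regions, libraries with the same replicate number deviated together weakly at most, although both replicate 1 libraries of G1E were rich in chromosome 4 peaks. The correlation of their deviations from the group means was -0.0524 to 0.0855 over 12 pairs, and 7 of these pairs matched best with their own number. No test was made of this, and a weak pairing is not excluded. With the replicate block the excess by line, 0.0551, had an exact permutation p = 0.0625, the smallest its 64 arrangements can give, so this says nothing of the effect. The deficit of recovery, 19.0 points, had p = 0.0156, also the smallest possible, in the exact permutation test. No other call changed with the block.

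With 300 bp around each summit, the excess by stage was 0.0476 (exact permutation p = 0.01), mitotic-only regions numbered 130 in both lines and 2337 in G1E-ER4, G1E-only regions 149 at both stages and 2515 in mitotic cells, and G1E-ER4-only regions 2183 in mitotic cells. The share of the 10000 strongest asynchronous peaks found in mitosis was 90.4%, and that of the 10000 weakest 14.9%. Among the 20000 highest peaks the excess by stage was 0.0802 (exact permutation p = 0.02) the difference between lines in the deficit -5.86 points, and the width difference by stage 265 bp. Asynchronous-only regions then numbered 174 in both lines, 1340 in G1E and 1844 in G1E-ER4, and mitotic-only regions 147, 916 and 529. G1E-only regions numbered 1434 in asynchronous and 548 in mitotic cells, and G1E-ER4-only regions 60 at both stages, 1150 and 469. Without chromosomes 1, 2, 4, 12 and 14, fewer regions remain by construction. Asynchronous-only regions numbered 5193 in G1E, mitotic-only regions 28 in both lines and 441 in G1E-ER4, G1E-only regions 58, 3432 and 978, and G1E-ER4-only regions 35, 3455 and 572. Without the replicate 1 libraries of G1E, the excess by line was 0.0754 (exact permutation p = 0.05) and -0.00325 in mitotic cells, and the width difference by line 202 bp. Asynchronous-only regions numbered 14145 in G1E, mitotic-only regions 116 in both lines and 13058 in G1E, G1E-only regions 539, 9935 and 5002, and G1E-ER4-only regions 370, 7946 and 2224.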

Other observations

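All tests of this part were chosen after the main results were seen, and those so marked after their own values too. Sites that distinguish asynchronous cells of the 2 lines were looked up in the mitotic lists, and the 2 sets were not tested against each other. The 5700 regions of all asynchronous G1E and no asynchronous G1E-ER4 lists were found in mitotic G1E lists at 16.6% ± 4.03 and in mitotic G1E-ER4 lists at 5.55% ± 0.993 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). The 5205 regions of the opposite kind were found in mitotic G1E-ER4 lists at 70.7% ± 9.01 and, although no asynchronous G1E list had them, in mitotic G1E lists at 57.8% ± 5.71 (SD, n = 3 each; exact permutation p = 0.2). Without chromosome 2 these shares were 68.5% and 63.6% (exact permutation p = 0.4). Asynchronous G1E lists covered the least sequence on average, 71.9 ± 36.3 Mb, against 109 ± 22.6 Mb in mitotic G1E and 118 ± 54.6 Mb in asynchronous G1E-ER4 (SD, n = 3 each). Absence of a region from them therefore need not mean a closed site. The 27042 regions of all 6 asynchronous lists were found at 84.5% ± 8.85 in mitotic G1E and 77.3% ± 3.10 in mitotic G1E-ER4 lists (SD, n = 3 each).

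Regions lost or gained in mitosis in G1E were then looked up in G1E-ER4. The 7880 regions of asynchronous and no mitotic G1E lists were found in asynchronous G1E-ER4 lists at 34.1% ± 4.65 and in mitotic ones at 6.55% ± 1.18 (SD, n = 3 each; exact permutation p = 0.1). The 5809 regions of mitotic and no asynchronous G1E lists were found in asynchronous G1E-ER4 lists at 63.9% ± 20.4 and in mitotic ones at 74.3% ± 12.2 (SD, n = 3 each; exact permutation p = 0.5). They were wide, with a median of 2799 bp, and most were also present in asynchronous cells of the other line. As the asynchronous G1E lists covered the least sequence, these regions need not be sites that open in mitosis. The reverse lookup gave 75.5% ± 3.47 and 33.8% ± 12.9 for the 5020 asynchronous-only regions of G1E-ER4 in asynchronous and mitotic G1E lists, and 19.8% ± 1.88 and 40.0% ± 4.76 for its 1123 mitotic-only regions (SD, n = 3 each; exact permutation p = 0.1 for both).

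The higher density of peaks on distal chromosome 2 in G1E-ER4 ran over most of that part. With its start set from the lists of one stage and its 26 bins of 1 Mb read in the other, which gave 156000001 both ways, 92.3% of bins had a higher mean in asynchronous and 100% in mitotic G1E-ER4, which argues against a few strong domains. It held 19.5% of the 5205 asynchronous and 33.4% of the 1423 mitotic G1E-ER4-only regions, against 2.30% of all regions, so openings spread evenly over the genome would not give this excess, although 80.5% and 66.6% of these regions lay elsewhere; both tests were set after their values were seen. A gain of copies of this part in G1E-ER4, or a loss in G1E, may account for it: the 364 regions there that all 12 lists share ranked 16.3 percentiles higher in G1E-ER4, beyond the range of -2.87 to 3.40 on the other chromosomes. The part was chosen from these same lists for its higher density in G1E-ER4, and the other chromosomes were taken whole. A higher rank there could thus follow from other causes, and the shift does not single out copy number. A broad effect of GATA1 or estradiol on this part cannot be excluded, since every G1E-ER4 sample had both.

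Chromosome X held fewer peaks in mitotic lists, 0.436% ± 0.101 against 1.02% ± 0.0987 in G1E and 0.406% ± 0.0427 against 0.638% ± 0.00855 in G1E-ER4 (SD, n = 3 each; lower in 6 of 6 mitotic lists; exact permutation p = 0.005, adjusted 0.1 over 60 comparisons). A lower rank of X peaks does not account for all of it. X regions were found in mitotic lists less often than autosomal regions of the same rank, at 53.6% against 65.0% in G1E and 65.9% against 80.4% in G1E-ER4. The difference was -12.9 points on average (SD 3.98, n = 6), against -0.737 in left-out asynchronous lists (SD 3.53, n = 6). The match was on rank alone, not on width or peak density. How much of the fall comes from rank was not measured. Lower signal of the whole X in mitosis stays open. Strong X regions, with a mean asynchronous rank within 20000, ranked lower than autosomal ones of the same rank in 4 of 6 mitotic lists. Within 10000 they did so in 2 of 6, and this test was set after the values were seen. The shift of 0.278 percentiles among X regions of all 12 lists leaves out those lost in mitosis and decides nothing. Lower signal of a chromosome at both stages would give a positive relation between the median percentile of its shared regions and the rank-matched difference. A high percentile here is a high signal. Over 20 chromosomes the relation was negative, with Spearman rho of -0.481 (permutation p = 0.034) and Pearson r of -0.737 (p = 0.0016). Chromosomes of higher signal thus kept fewer regions, opposite to this prediction, which was set before these values were seen. Without chromosomes 1 and 12 the values were -0.288 (permutation p = 0.24) and -0.0236 (p = 0.93). The filter on shared regions can itself set this median, so the relation does not decide the question. A dependence of mitotic recovery on peak density, through chance overlap or copy number, is a candidate explanation that is not particular to X: the difference ran from -12.9 on X and -9.42 on chromosome 3 to 17.6 on chromosome 12 and followed the peaks per Mb of the asynchronous lists, with Pearson r = 0.955 and Spearman rho = 0.926 (permutation p = 1e-05 each, the smallest possible, adjusted 2e-05), a test set after the trend was noticed, and r = 0.898 without X and chromosome 12; chromosomes are not independent replicates.

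Chromosome 4 was rich in peaks in replicate 1 of G1E at both stages, with 13676 and 15869 peaks, or 13.7% and 15.9%, against 4.67% to 7.46% in the other 10 lists. Weaker peaks further down the list do not account for it in the mitotic library, whose share among its 20000 highest peaks was 18.7%, against 5.89% to 6.91% in the others. In the asynchronous library that share was 8.20%, above the others but well below the 13.7% of its whole list, so a contribution of weaker peaks stays open there; both tests were set after these values were seen. Additional copies of chromosome 4 in these samples may account for it: the 1080 shared regions there had a median percentile of 66.9 and 64.3 in the 2 lists, at least 13.9 above every other G1E list. That both libraries carry the same replicate number could reflect a common culture, which the labels do not state, and no biological explanation was tested, since the design names no group that these 2 libraries form.

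Other chromosomes also differed by stage. Chromosome 10 was lower in mitotic lists by the same test as X, with a difference of -0.565 points (exact permutation p = 0.005, adjusted 0.1). Among the 20000 highest peaks 6 chromosomes, namely 3, 6, 9, 10, 16 and 18, had lower shares in mitotic lists, by -0.388 to -0.863 points, and chromosomes 1 and 12 higher ones, by 2.35 and 3.58 points (exact permutation p = 0.005 and adjusted 0.0333 each, over 60 comparisons). Shares sum to 100%, so part of these falls follows from the rises and they are not separate changes. X did not pass there, at -0.476 points (exact permutation p = 0.015, adjusted 0.0818).

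The strongest peak of all 16 lists lay at the start of chromosome 9, from 3002015 to 3003297 in replicate 1 of asynchronous G1E. It topped every list whatever the line or stage, and no filter against mapping artefacts was applied here.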
